A study of Homo sapiens with 28 samples.

How the data were processed

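Gene expression was measured by sequencing poly(A)-selected RNA from H9 cells, wild type or SOX1-/-, in 14 groups of genotype, day and culture label with 2 libraries each. All 28 deposited columns were matched to the samples by their names, and 0 columns were left unmatched. Numbers 1 and 2 of WT and 26 and 48 of KO were read as lines. The labels name both a HiSeq2000 and an X-ten run format without saying which sample had which, so no batch could be fitted.

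The authors deposited gene-level TPM, transcript abundance scaled for length and to a fixed column total, for 58219 genes. The submitters' processing notes name CASAVA 1.7, Salmon 0.8.2 and the genome build hg38. What each tool was used for is not given in the sources used here. The annotation release is not given in the sources used here. Of the gene IDs, 55050 matched GENCODE 29 with the version and 57881 without it, and 275 gene names occur in more than 1 row. TPM keeps no read depth, so the counting precision of each library is unknown and no interval from counting is given.

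A gene was tested if its TPM was at least 1 in at least 2 libraries, which 27912 genes were. Comparisons were fitted with limma 3.58.1 in R 4.3.3 with data.table, version 1.17.8, on log2(TPM + 1). A model with 1 mean per group over all 28 libraries left 14 residual degrees of freedom, with 2.76 prior degrees of freedom, and an intensity trend in the moderated variance. No covariate was fitted. Adjusted p follows Benjamini and Hochberg within each of 19 comparisons, and genes at adjusted p < 0.05 were called. KO and WT were compared in each of 7 groups and as line means over the 3 labels on days 4 and 8, where the line is the replicate and 6 residual degrees of freedom remain. The other comparisons were 4 of labels within WT, 3 of the KO effect between labels on day 8, 2 of time in WT and 1 of the KO effect between days. In those of time and between days each library counts as a replicate, although a line gives 3 libraries on days 4 and 8. An exact permutation test of 2 against 2 cannot give a p below 0.333, so none was used.

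Lists of genes were fixed at 18: forebrain, midbrain, isthmus, rostral hindbrain, HOX groups 3 to 9 and CDX, SOX B, pan-neural, neuronal, pluripotency, mesendoderm, surface ectoderm, neural crest, dorsal, ventral, WNT feedback, NOTCH, cell stress and cell cycle. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The HOX and CDX list had 2 of 21 members tested, too few for these tests. Lists, comparisons, tests, filter and the alternatives named next were chosen before the data were examined.

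Genes were named by a rule: SOX1, the 8 highest and 8 lowest called genes with an absolute log2 fold change of at least 1 and libraries (line means for averages) that did not overlap, clone, pseudogene, ribosomal protein and similar identifiers aside, up to 4 called members of each list by fold change and 2 uncalled ones by TPM, and OTX2, EN1, EN2, PAX2, GBX2, HOXA2, HOXB1, SOX2 and SOX3 throughout. HOXB1 did not pass the filter. Some genes that the rule names are not reported here. A gene whose name occurs in more than 1 row was left out.

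Alternatives were a pseudocount of 0.1, no filter, median-ratio scaling of the TPM columns, a fit of only the libraries compared, the line as a block, each line left out, an absolute log2 fold change of at least 1, no intensity trend with robust variances, and adjusted p < 0.01 for shared calls. Chosen after seeing the data were protein-coding genes only, library quality weights, a correction for GC content and transcript length per library, leaving out the 4 WT day 4 CT libraries, the SOX B list without SOX1 in the comparisons of KO, and line means fitted for 1 day alone or with the line as a block. Pairing of lines between groups was checked by correlating line differences across genes: with a mean TPM of at least 10 it ran from -0.094 to 0.078 in WT, with 0 of 21 pairs of groups over 0.1, and from -0.057 to 0.204 in KO, with 8 of 21. The block was therefore an alternative and not the first choice.

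The fit was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among 27912. Noise was independent and normal with 1 SD per gene, and lines had no effect of their own. Changed genes had a mean log2(TPM + 1) of at least 2. The shares below hold for these settings and need not hold for the calls in the deposited data. For KO against WT in CT1.0 on day 8 it called 67% and 94% of them, and 7.47% of its calls were false. For line means on day 8 the values were 73%, 93% and 0.599%, for WT CT1.0 against IWP2 on day 8 64%, 92% and 3.11%, for the KO effect between CT1.0 and CT0.4 40%, 81% and 7.63%, and for WT day 8 against day 4 95%, 94% and 5.03%.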

Results

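H9 cells, an established human embryonic stem cell line, were collected with SOX1 (wild type, WT) or without it (SOX1-/-, here KO) to ask what this gene does early in neural differentiation; the series title concerns the regional identity of neural progenitors. SOX1 is a transcription factor of the SOX B group and an early marker of neural tissue. Cells were taken undifferentiated (ES, day 0) and at days 4 and 8 under 3 labels: IWP2, CT0.4 and CT1.0. IWP2 is a known inhibitor of WNT secretion. CT is not spelled out, and its number has no unit, in the sources used here. Each of the 14 groups holds 2 libraries, 28 in all, numbered 1 and 2 in WT and 26 and 48 in KO and treated here as lines. The values are gene-level TPM as deposited, tested with limma on log2(TPM+1), a scale that understates the change of low genes. Values are means ± SD of n = 2 libraries per group, with KO or the label named first ahead of the other, and "called" means an adjusted p under 0.05. The p-values measure the spread between these few lines and their libraries, not between other cells.

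Of 58219 genes, 27912 passed the filter and were tested. Replicate pairs correlated across genes at 0.955 to 0.970, and genes are not independent replicates. The 4 WT day 4 libraries of CT0.4 and CT1.0 stood apart: 17694 to 18233 genes reached a TPM of 1 in them, against 18876 to 20338 in the other 24 libraries. Protein-coding genes held 94.1 to 94.8% of their TPM, against 92.3 to 93.9% elsewhere. Of these libraries the median-ratio size factors were 0.818 to 0.926, against 0.92 to 1.14. Ribosomal protein genes, which code for parts of the ribosome, held 27.7 to 30.3% of TPM in KO CT1.0 at day 8 and 21.6 to 23% in WT CT1.0 at day 8. Mitochondrial genes held 4.96 and 4.81% in KO CT1.0 at day 4 and 7.31 and 7.26% in WT CT1.0 at day 4, with 4.81% the lowest of all libraries.

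SOX1 was near 0 in ES cells, with TPM of 0.264 and 0.177 in WT lines 1 and 2 and of 0.0238 and 0.051 in KO lines 26 and 48. In WT it was highest in CT1.0, at 84.1 and 98 TPM on day 4 and 72.1 and 79.4 TPM on day 8. WT CT0.4 held 4.88 and 7.01 TPM on day 4 and 11.3 and 15.7 TPM on day 8, and WT IWP2 held 0.907 and 0.99 TPM on day 4 and 10.6 and 9.9 TPM on day 8. SOX1 in KO lines 26 and 48 on day 4 stood at 0.41 and 1.14 TPM in IWP2, 0.866 and 1.49 TPM in CT0.4, and 0.705 and 3.08 TPM in CT1.0. By day 8 these lines held 1.96 and 2.77 TPM in IWP2, 0.813 and 2.09 TPM in CT0.4, and 1.14 and 2.77 TPM in CT1.0. The KO libraries thus keep some SOX1 reads, and what remains of the transcript cannot be read from gene-level TPM. KO against WT in CT1.0, SOX1 was lower on day 4 (log2 -5.12, adjusted p = 1.02e-06) and day 8 (log2 -4.76, adjusted p = 2.58e-06). In CT0.4 it was lower on day 4 (log2 -1.67, adjusted p = 0.0169) and day 8 (log2 -2.60, adjusted p = 0.00221). These CT0.4 calls each ended without a WT line: without line 1 the values were -1.89 (adjusted p = 0.263) and -2.82 (adjusted p = 0.108), and without line 2 they were -1.45 (adjusted p = 0.285) and -2.37 (adjusted p = 0.342). With only the libraries compared no CT call of SOX1 was kept (adjusted p = 0.0879 and 0.132 in CT1.0 and 0.251 and 0.455 in CT0.4, on days 4 and 8). SOX1 was not called in IWP2 on day 8 (log2 -1.75, adjusted p = 0.134). There the value without KO line 26 was -1.58 (adjusted p = 0.0322) and without KO line 48 was -1.93 (adjusted p = 0.0121). It was not called in IWP2 on day 4 (log2 -0.17, adjusted p = 1) or in ES cells (log2 -0.23, adjusted p = 0.922).

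**Figure D1:**
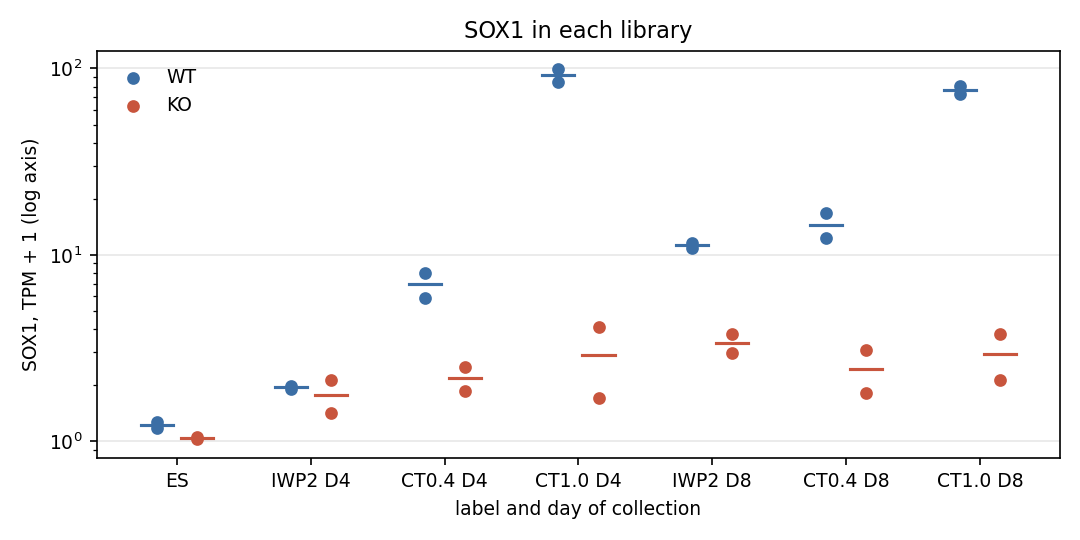
SOX1 in each of the 28 libraries, as TPM + 1 on a log axis, with a short line at the mean of each group of 2. WT CT1.0 held 84.1 and 98 TPM on day 4, and no KO library held more than 3.08 TPM.

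The WT cultures of day 8 show which regional genes each label carries. In WT CT0.4, most genes of the midbrain and dorsal lists stood above their level in IWP2, some of them far above. Examples are WNT1 (484 ± 90 against 0.104 ± 0.0498 TPM, log2 fold change 8.77, adjusted p = 4.38e-11), a dorsal midline signal, and LMX1A (224 ± 76.9 against 0.197 ± 0.0143 TPM, log2 7.51) and MSX1 (234 ± 116 against 0.864 ± 0.0187 TPM, log2 6.88), transcription factors of the roof plate and dorsal midbrain. Forebrain genes stood lower, among them SIX3 (0.757 ± 0.324 against 127 ± 1.52 TPM, log2 fold change -6.20, adjusted p = 1.02e-11), which acts in the anterior forebrain, and LHX2 (1.64 ± 1.28 against 118 ± 17.4 TPM, log2 -5.58) and FEZF1 (3.1 ± 0.253 against 265 ± 11.3 TPM, log2 -6.02), forebrain transcription factors. OTX2 (log2 0.80, adjusted p = 0.195), a forebrain and midbrain factor, was not called, nor were EN1 (log2 0.75, adjusted p = 0.251), EN2 (log2 0.07, adjusted p = 0.924) and HOXA2 (log2 -0.06, adjusted p = 1). The midbrain list genes EN1 and EN2 were near 0 in WT CT0.4, at 0.725 ± 0.0283 and 0.0737 ± 0.0363 TPM. Of 16 midbrain genes, 13 were higher, with OTX1 (6.79) among them, and none lower (14 and 0 adjusted over the list alone; adjusted p = 9.19e-28). All 10 dorsal genes were higher. So were 10 of 13 WNT feedback genes, which WNT signalling itself switches on, with AXIN2 (295 ± 77.2 against 10.6 ± 1.34 TPM, log2 4.65) and SP5 (22.9 ± 1.09 against 0.0377 ± 4.49e-04 TPM, log2 4.52) among them. Of 16 forebrain genes, 4 were higher and 9 lower (4 and 11 over the list alone). The isthmus list had 0 higher and 8 of 11 lower, with FGF8 (1.52 ± 0.706 against 160.3 ± 24.2 TPM, log2 -6.02), the signal of the midbrain-hindbrain boundary, and SPRY1 (1.67 ± 0.995 against 139 ± 9.91 TPM, log2 -5.76), its feedback inhibitor. These 5 lists stayed called with an estimated correlation. Neuronal differentiation (8 higher, 1 lower of 14), pluripotency (0 and 4 of 14), NOTCH (1 and 6 of 11) and cell cycle (0 and 4 of 14) were called and lost the call then (adjusted p = 0.127, 0.106, 0.201 and 0.201 with an estimated correlation). Within them HES5 (15 ± 9.61 against 82.9 ± 6.95 TPM, log2 -2.54), a NOTCH target, was lower. The pan-neural list, not called, had 6 higher, with PAX6 (379 ± 37.6 against 63.1 ± 1.34 TPM, log2 2.57), and 6 lower of 16 (6 and 7 over the list alone). In all, 1757 genes were higher and 1643 lower. The count of 3400 became 983 (without WT line 1) and 1389 (without WT line 2). Not called when a line was left out were HES5 (0.458, WT line 1) and PAX6 (0.0674, WT line 2), with the highest adjusted p.

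WT CT1.0 carried genes of the hindbrain and ventral neural tube on day 8. Against IWP2, HOXA2 (26.6 ± 1.48 against 0.0449 ± 0.0635 TPM, log2 fold change 4.72, adjusted p = 9.47e-06), a hindbrain HOX gene, and HOTAIRM1 (138 ± 33 against 0.231 ± 0.327 TPM, log2 6.82), a long RNA from the same cluster, were higher. So was CYP26A1 (49.6 ± 15.2 against 0.421 ± 0.385 TPM, log2 5.15), which breaks down retinoic acid. EN1 (2.27 ± 0.655 against 0.0284 ± 1.82e-04 TPM, log2 1.66) and GBX2 (5.1 ± 0.532 against 1.4 ± 0.0307 TPM, log2 1.34), genes of the isthmus and anterior hindbrain, were also higher, at low levels. Lower genes were OTX2 (6.09 ± 0.145 against 234 ± 10.5 TPM, log2 fold change -5.05, adjusted p = 6.44e-08), SIX3 (0.15 ± 0.00685 against 127 ± 1.52 TPM, log2 -6.80) and FGF8 (2.08 ± 0.432 against 160.3 ± 24.2 TPM, log2 -5.71). RAX (0 ± 0 against 43.9 ± 4.26 TPM), an eye field gene, was listed at 0 in both WT CT1.0 libraries. Forebrain genes fell in 11 and rose in 2 of 16 (adjusted p = 2.73e-12). The ventral list, with SHH (3.02 ± 2.24 against 0.0187 ± 3.35e-04 TPM, log2 1.86), a ventral midline signal, and its target PTCH1 (75.9 ± 0.242 against 29.6 ± 2.64 TPM, log2 1.33), had 6 of 7 higher. Of 7 rostral hindbrain genes 4 were higher and 1 lower (5 and 1 over the list alone). Neuronal genes had 7 of 14 higher, with NHLH1 (2.63) and ELAVL4 (2.60), and WNT feedback genes 6 higher and 1 lower of 13. The isthmus list had 1 higher and 6 lower of 11, and surface ectoderm 0 and 5 of 10, with KRT18 (9.16 ± 2.8 against 96.6 ± 1.48 TPM, log2 -3.29), a keratin of simple epithelia. These 7 lists stayed called with an estimated correlation. Midbrain (6 higher, 1 lower of 16), neural crest (3 and 1 of 12), dorsal (4 and 2 of 10), pluripotency (0 and 5 of 14) and cell cycle (0 and 9 of 14) lost the call then (adjusted p = 0.0746, 0.0869, 0.33, 0.124 and 0.0869 with an estimated correlation). Mesendoderm, with 1 higher, APLNR (2.22 ± 0.791 against 0.594 ± 0.284 TPM), and 1 lower, GSC (0.0262 ± 0.037 against 2.74 ± 0.409 TPM), of 4, was not called. Of the HOX groups 3 to 9 and CDX 2 genes were tested, too few for a test of the list, and HOXB3 (log2 -0.01, adjusted p = 1) was not called. Among all genes 830 were higher and 2183 lower. After median-ratio scaling the split was 1235 and 1334, with cell cycle at 0 higher and 4 lower. Leaving out 1 line changed the 3013 calls to 731 (without WT line 1) and 826 (without WT line 2). Named genes whose call ended, with the highest adjusted p and the line left out, were GBX2 (0.434, WT line 1), EN1 (0.354, WT line 1), APLNR (0.191, WT line 2), PTCH1 (0.171, WT line 2), GSC (0.11, WT line 2) and NHLH1 (0.0652, WT line 1).

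Between the CT labels, WT CT1.0 on day 8 held less of most midbrain list and all dorsal list genes, and more of the SOX B genes, than WT CT0.4. Lower were OTX2 (6.09 ± 0.145 against 408 ± 6.63 TPM, log2 fold change -5.85, adjusted p = 9.81e-09), LMX1A (0.637 ± 0.269 against 224 ± 76.9 TPM, log2 -7.07), WNT1 (6.23 ± 1.77 against 484 ± 90 TPM, log2 -6.08) and ZIC1 (2.98 ± 3.18 against 277 ± 80.3 TPM, log2 -6.38), the last a dorsal neural gene. Higher were HOTAIRM1 (138 ± 33 against 0.106 ± 0.149 TPM, log2 6.96), SOX21 (82.3 ± 6.64 against 10.8 ± 4.05 TPM, log2 2.86) and SOX3 (61.9 ± 4.69 against 30.1 ± 8.46 TPM, log2 1.04). The midbrain list fell in 14 of 16 (1 higher and 14 lower over the list alone), the dorsal list in 10 of 10 and the WNT feedback list in 8 of 13. All 4 tested SOX B genes rose, among them SOX1 (75.7 ± 5.14 against 13.5 ± 3.15 TPM, log2 2.42) and SOX2 (228 ± 16.9 against 129 ± 28 TPM, log2 0.83). Ventral genes rose in 4 of 7, with NKX6-2 (6.24 ± 3.9 against 0.404 ± 0.319 TPM, log2 2.27), and surface ectoderm genes fell in 4 of 10, with 1 higher. The forebrain list had 2 higher and 6 lower. These lists stayed called with an estimated correlation. The isthmus list (3 higher, 1 lower of 11) and the NOTCH list (4 and 1 of 11) lost the call then (adjusted p = 0.297 and 0.386 with an estimated correlation). HOXA2 (26.6 ± 1.48 against 0 ± 0 TPM) was listed at 0 in both WT CT0.4 libraries. Of all genes, 1172 were higher and 2817 lower, and 1617 and 1981 after median-ratio scaling. With 1 line left out, the 3989 calls became 1255 (without WT line 1) and 1590 (without WT line 2). A left-out line ended the call of SOX3 (0.357, WT line 1) and SOX1 (0.107, WT line 1), with the highest adjusted p given.

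The labels already differed in WT on day 4. WT CT1.0 held more SOX1 (91 ± 9.86 against 0.949 ± 0.0591 TPM, log2 fold change 5.56, adjusted p = 3.17e-08), HOXA2 (21.7 ± 4.42 against 0.129 ± 0.0697 TPM, log2 4.32) and CYP26A1 (287 ± 38.6 against 0.695 ± 0.00903 TPM, log2 7.40) than WT IWP2. It held less RAX (0.0801 ± 7.00e-04 against 162 ± 3.74 TPM, log2 fold change -7.24, adjusted p = 1.25e-10), SIX3 (0.472 ± 0.308 against 156 ± 0.24 TPM, log2 -6.76), OTX2 (8.19 ± 5.15 against 159 ± 5.72 TPM, log2 -4.25) and PAX6 (6.8 ± 1.88 against 92.9 ± 2.5 TPM, log2 -3.61), factors of the eye field, forebrain and early neural tube. PAX2 (4.71 ± 0.323 against 50 ± 1.91 TPM, log2 -3.16), an isthmus gene, was also lower. EN1 (2.43 ± 0.944 against 0 ± 0 TPM) was listed at 0 in both WT IWP2 libraries, and GBX2 (log2 0.74, adjusted p = 0.21) was not called. The forebrain list had 1 higher and 8 lower of 16, and rostral hindbrain 4 higher and 1 lower of 7. Both stayed called with an estimated correlation (adjusted p = 0.00488 and 0.0151 with an estimated correlation). The midbrain list, called upward, had a median of 0 and a mean of 0.015. Isthmus (2 higher, 6 lower of 11), midbrain (3 and 1 of 16), WNT feedback (3 and 1 of 13), neural crest (1 and 1 of 12), NOTCH (3 and 2 of 11) and cell cycle (0 and 8 of 14) lost the call then (adjusted p = 0.461, 0.461, 0.203, 0.354, 0.461 and 0.461 with an estimated correlation). The all-genes median was -0.22, and 788 genes were higher and 4808 lower. After median-ratio scaling the median was 0 and the split 1791 and 1546, with cell cycle at 1 higher and 0 lower, pluripotency at 3 and 2 in place of 1 and 3, and cell stress at 1 and 0 in place of 1 and 3. Dropping 1 line turned 5596 calls into 1194 (without WT line 1) and 1826 (without WT line 2). The call ended for EN1 (0.259, WT line 1) (highest adjusted p and the line left out).

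The comparison of KO and WT ES cells asks what differed before differentiation, where SOX1 was near 0 in both. BNIP3 (28.5 ± 1.63 against 109 ± 48 TPM, log2 fold change -1.83, adjusted p = 0.0012), a mitophagy gene switched on by low oxygen, was lower in KO. So were metallothionein genes, which bind metals: MT1X (38.6 ± 11.1 against 186 ± 114 TPM, log2 -2.12), MT1H (6.72 ± 0.705 against 47.5 ± 26.8 TPM, log2 -2.53) and MT1E (2.25 ± 0.365 against 16.8 ± 9.11 TPM, log2 -2.36). IRX2 (9.48 ± 4.51 against 23.4 ± 7.62 TPM, log2 -1.25), a patterning factor, and C5orf38 (3.71 ± 1.15 against 19.1 ± 7.25 TPM, log2 -2.07), its neighbour, were lower too. TRBJ2-7 (14.9 ± 15.3 against 0 ± 0 TPM) and ST6GAL2-IT1 (6.85 ± 0.776 against 0 ± 0 TPM) were listed at 0 in both WT libraries, and TRBJ2-5 (0 ± 0 against 3.63 ± 0.268 TPM) in both KO libraries. Pluripotency factors stood close together, POU5F1 (log2 0.03, adjusted p = 1) and LIN28A (log2 -0.04, adjusted p = 0.985) among them, and none of 14 was called. OTX2 (log2 0.08, adjusted p = 1) and SOX2 (log2 -0.35, adjusted p = 0.276) were not called either. The pluripotency list was called upward as a whole and SOX B (0 of 4 called), pan-neural (0 of 16) and rostral hindbrain (0 higher, 1 lower of 7) downward, each at adjusted p = 0.01, and cell stress downward at 0.0413 with 0 called (1 and 3 over the list alone). None kept the call (adjusted p = 0.365, 0.388, 0.365, 0.304 and 0.388 with an estimated correlation). Of all genes 14 were higher and 47 lower, and 30 and 69 after median-ratio scaling. Fits with 3 lines gave 118 (without WT line 2), 113 (without KO line 26) and 149 (without KO line 48), against 61 with all 4. Calls lost on leaving out a line, with the highest adjusted p, were those of IRX2 (0.764, WT line 1), MT1X (0.759, WT line 1), MT1E (0.514, WT line 1), MT1H (0.402, WT line 1), TRBJ2-7 (0.219, WT line 1), BNIP3 (0.206, WT line 1), ST6GAL2-IT1 (0.154, KO line 26) and C5orf38 (0.0973, KO line 26).

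In IWP2, labelled with an inhibitor of WNT secretion, few genes told KO from WT on day 4. Forebrain genes were at like levels, with FEZF1 (422 ± 26.4 against 432 ± 16.9 TPM, log2 fold change -0.04, adjusted p = 1), OTX2 (140.4 ± 42.4 against 159 ± 5.72 TPM, log2 -0.21) and LHX2 (152 ± 39.1 against 171 ± 15.2 TPM, log2 -0.19) not called. PAX2 (42.7 ± 1.72 against 50 ± 1.91 TPM, log2 -0.22) and SOX2 (438 ± 18.9 against 420.3 ± 11.1 TPM, log2 0.06) were not called either, nor was SOX3 (log2 -0.07, adjusted p = 1). A gene called higher was C11orf71 (6.76 ± 1.71 against 2.72 ± 0.247 TPM, log2 fold change 1.04, adjusted p = 0.0349). None of the 17 lists tested was called. Limma called 8 genes higher and 4 lower, with 2317 at unadjusted p < 0.05, and 0 when fitted with only the libraries compared, with 2188. The count of 12 became 58 (without WT line 1), 47 (without WT line 2), 110 (without KO line 26) and 143 (without KO line 48). Not called when a line was left out were C11orf71 (0.419, WT line 2), with the highest adjusted p.

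On day 8 in IWP2 the regional gene OTX2 (243 ± 19.2 against 234 ± 10.5 TPM, log2 fold change 0.05, adjusted p = 1) and the neural gene SOX2 (397 ± 8.55 against 397 ± 2.89 TPM, log2 -0.00) were again not called. PAX3 (log2 1.04, adjusted p = 0.434), a dorsal gene, was not called either. TAB3-AS2 (2.64 ± 1.45 against 0 ± 0 TPM), an antisense RNA called higher in KO, was listed at 0 in both WT libraries. The strand of counting is not stated, so its reads are not told apart here from those of an overlapping gene. None of the 17 lists tested was called. In all, 12 genes were higher and 5 lower (6 and 5 after median-ratio scaling), with 1408 at unadjusted p < 0.05. Leaving out 1 line changed the 17 calls to 47 (without WT line 1), 59 (without WT line 2), 118 (without KO line 26) and 107 (without KO line 48). Named genes whose call ended, with the highest adjusted p and the line left out, were TAB3-AS2 (0.0652, WT line 1).

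On day 4 in CT0.4 DDIT4 (483 ± 25.4 against 36.5 ± 8.36 TPM, log2 fold change 3.71, adjusted p = 0.000259), a stress gene that restrains mTOR, was higher in KO. So were SLC16A3 (36.8 ± 4.52 against 2.51 ± 1.5 TPM, log2 3.49), a lactate exporter, PFKFB4 (75.3 ± 19.4 against 10.2 ± 0.211 TPM, log2 2.75) and AK4 (14.6 ± 0.469 against 1.15 ± 0.51 TPM, log2 2.87), enzymes of energy metabolism, and BHLHE40 (10.1 ± 2.93 against 0.0377 ± 0.0241 TPM, log2 3.40), a transcriptional repressor. ID1 (14.9 ± 5.32 against 1.67 ± 0.374 TPM, log2 2.54), a target of BMP signalling, was higher too. The regional genes OTX2 (log2 0.06, adjusted p = 1), EN1 (log2 0.78, adjusted p = 0.286) and PAX2 (log2 0.28, adjusted p = 0.774) were not called. WNT1 (24.5 ± 10.5 against 8.42 ± 1.59 TPM, log2 1.38) and BARHL1 (8.9 ± 1.79 against 3.46 ± 0.525 TPM, log2 1.14), a developmental transcription factor, were higher. Of 12 cell stress genes 4 were higher (5 over the list alone), with ATF3 (0.83) and HSPA1B (0.64), and of 14 cell cycle genes 1 was higher, PLK1 (0.51), and 1 lower, PCNA (-0.64). None of the 17 lists was called by camera. The all-genes median was 0.13, with 1025 genes higher and 158 lower, and after median-ratio scaling it was 0, with 464 higher and 1033 lower. Fitted with only the libraries compared, 0 genes were called, with 4257 at unadjusted p < 0.05. After scaling the cell stress list had 1 higher and 1 lower, midbrain 0 and 0 in place of 2 and 0, pan-neural 1 and 1 in place of 2 and 0, and cell cycle 0 and 3. With 1 line left out, the 1183 calls became 109 (without WT line 1), 421 (without WT line 2), 327 (without KO line 26) and 755 (without KO line 48). A left-out line ended the call of WNT1 (0.472, WT line 1), HSPA1B (0.449, WT line 1), ATF3 (0.397, WT line 1), PLK1 (0.378, WT line 1), PCNA (0.303, WT line 1), BARHL1 (0.244, KO line 48), SLC16A3 (0.0563, WT line 2) and DDIT4 (0.0502, WT line 1), with the highest adjusted p given.

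By day 8 in CT0.4, KO held less of the midbrain list gene BARHL1 (9.54 ± 1.2 against 52.4 ± 31 TPM, log2 fold change -2.21, adjusted p = 0.00106) and the forebrain list genes LHX5 (3.38 ± 1.14 against 20 ± 14.3 TPM, log2 -2.10) and EMX2 (2.74 ± 0.405 against 11.8 ± 5.34 TPM, log2 -1.72). The WT libraries spread widely for these genes, as the SDs show. SOX21 (2.77 ± 0.898 against 10.8 ± 4.05 TPM, log2 -1.63), a SOX B gene, and HES5 (1.08 ± 0.117 against 15 ± 9.61 TPM, log2 -2.80), a NOTCH target, were lower in KO. DLX2 (10 ± 0.268 against 3.02 ± 2.56 TPM, log2 1.62), also on the forebrain list, RSPO3 (37.6 ± 7.84 against 11.1 ± 5.6 TPM, log2 1.75), which amplifies WNT signalling, and TTR (84.3 ± 26.6 against 27.2 ± 19.5 TPM, log2 1.76), a thyroid hormone carrier, were higher. OTX2 (log2 -0.20, adjusted p = 0.973), WNT1 (log2 0.24, adjusted p = 0.941) and EN1 (log2 0.49, adjusted p = 0.765) were not called. Forebrain genes had 1 higher and 5 lower of 16 (1 and 7 over the list alone), SOX B 0 and 2 of 4 (0 and 4), where 1 of the 2 is SOX1, the gene removed, and cell cycle 0 and 1 of 14 (0 and 11), with PLK1 (-0.56). These 3 lists stayed called with an estimated correlation (adjusted p = 0.000563, 0.0189 and 0.0354 with an estimated correlation). Without SOX1 the SOX B list had 1 lower of 3 (adjusted p = 0.0424 with an estimated correlation). NOTCH (0 higher, 2 lower of 11; 0 and 6 over the list alone) and pan-neural (0 and 2 of 16) were called downward, and dorsal, neural crest and neuronal lists upward with 0 genes called. None of these kept the call (adjusted p = 0.0593, 0.0641, 0.313, 0.166 and 0.444 with an estimated correlation). In all, 44 genes were higher and 72 lower. Dropping 1 line turned 116 calls into 71 (without WT line 2) and 215 (without KO line 48). The call ended for HES5 (0.714, WT line 2), EMX2 (0.657, WT line 2), PLK1 (0.568, WT line 2), RSPO3 (0.504, WT line 2), LHX5 (0.449, WT line 2), TTR (0.449, WT line 2), SOX21 (0.378, WT line 2), DLX2 (0.263, KO line 26) and BARHL1 (0.0725, KO line 48) (highest adjusted p and the line left out).

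CT1.0 is the label under which WT cells held the most SOX1. On day 4 the KO cells held more of the midbrain or isthmus genes OTX2 (105 ± 65.4 against 8.19 ± 5.15 TPM, log2 fold change 3.50, adjusted p = 2.42e-05), EN1 (28.9 ± 15.5 against 2.43 ± 0.944 TPM, log2 3.05), PAX2 (57.7 ± 26.2 against 4.71 ± 0.323 TPM, log2 3.29), WNT1 (38 ± 17.6 against 4.84 ± 1.05 TPM, log2 2.67) and DMBX1 (27.4 ± 16.2 against 1.22 ± 0.393 TPM, log2 3.56) there. Neither the midbrain nor the isthmus list kept its call (adjusted p = 0.0703 and 0.315 with an estimated correlation). KO cells held less HOXA2 (6.08 ± 7.33 against 21.7 ± 4.42 TPM, log2 fold change -2.22, adjusted p = 0.00942), CYP26A1 (68.3 ± 70.4 against 287 ± 38.6 TPM, log2 -2.57) and FEZF2 (0.939 ± 0.856 against 15.3 ± 3.8 TPM, log2 -3.12). The SOX B genes SOX3 (8.25 ± 2.47 against 26.1 ± 3 TPM, log2 -1.57) and SOX21 (48.5 ± 1.8 against 105 ± 6.58 TPM, log2 -1.09) were lower, and SOX2 (log2 -0.06, adjusted p = 0.83) was not called. The KO lines differed in degree: OTX2 stood at 151 TPM in line 26 and 58.5 TPM in line 48, and HOXA2 at 0.899 and 11.3 TPM. DDIT4 (697 ± 47.8 against 153 ± 14.2 TPM, log2 2.18) and the heat shock gene HSPA1B (99.8 ± 4.39 against 26.8 ± 2.06 TPM, log2 1.86) were higher as well. DKK1 (1.86 ± 1.8 against 0 ± 0 TPM), a WNT inhibitor, was listed at 0 in both WT libraries. Of 16 midbrain genes 10 were higher and none lower (adjusted p = 1.13e-07). Isthmus had 7 higher and 1 lower of 11 (8 and 1 over the list alone), WNT feedback 7 higher of 13 with SP5 (53.8 ± 30.1 against 1 ± 0.552 TPM, log2 4.68), and cell stress 6 higher of 12. SOX B had 3 lower of 4, SOX1 among them, and pan-neural 3 higher and 5 lower of 16, with NES (-0.99) lower. None of these 6 lists kept the call (WNT feedback, cell stress, SOX B and pan-neural adjusted p = 0.315, 0.304, 0.0703 and 0.315 with an estimated correlation). Without SOX1 the SOX B list had 2 lower of 3 (adjusted p = 0.304 with an estimated correlation). Rostral hindbrain, at 1 higher and 3 lower of 7, was not called, and its median (0.48) and mean (-0.21) differ in sign. The all-genes median was 0.2, with 3453 genes higher and 694 lower, and 0.013 after median-ratio scaling, with 1765 higher and 2547 lower. Fitted with only the libraries compared, 334 genes were called. After scaling the list medians moved from 1.90 to 1.82 in midbrain, 1.14 to 0.95 in isthmus, 0.87 to 0.61 in cell stress and, without SOX1, -1.09 to -1.36 in SOX B, and cell cycle went from 1 higher and 2 lower to 0 and 6. Fits with 3 lines gave 1023 (without WT line 1), 1439 (without WT line 2) and 1814 (without KO line 26), against 4147 with all 4. Calls lost on leaving out a line, with the highest adjusted p, were those of NES (0.327, WT line 2), DKK1 (0.228, WT line 1), HOXA2 (0.216, WT line 2), CYP26A1 (0.144, WT line 2), DDIT4 (0.119, WT line 1), SOX21 (0.101, WT line 2) and SOX3 (0.0535, WT line 2).

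On day 8 in CT1.0 KO cells held more dorsal, midbrain and isthmus genes than WT. Higher were WNT1 (94.8 ± 52.6 against 6.23 ± 1.77 TPM, log2 fold change 3.63, adjusted p = 2.45e-05), OTX2 (66.7 ± 22.6 against 6.09 ± 0.145 TPM, log2 3.21), EN1 (17.8 ± 6.34 against 2.27 ± 0.655 TPM), LMX1A (14.8 ± 9.15 against 0.637 ± 0.269 TPM, log2 3.15), FGF17 (15.1 ± 1.97 against 1.69 ± 0.065 TPM, log2 2.58) and ZIC1 (62.9 ± 16.3 against 2.98 ± 3.18 TPM, log2 4.26). Lower were SHH (0.0158 ± 4.38e-04 against 3.02 ± 2.24 TPM, log2 fold change -1.86, adjusted p = 0.00309), NKX6-2 (0.0116 ± 0.0164 against 6.24 ± 3.9 TPM, log2 -2.73) and NTN1 (3.23 ± 3.55 against 33.8 ± 1.59 TPM, log2 -3.36), ventral or floor plate genes. NES (312 ± 139 against 959 ± 93.5 TPM, log2 -1.69) and TUBB3 (168 ± 100.3 against 560.0 ± 65.2 TPM, log2 -1.86), a neural progenitor filament and a neuronal tubulin, were lower too. EN2 (2.35 ± 1.17 against 0.286 ± 0.114 TPM, log2 1.34) and PAX2 (8.54 ± 1.07 against 2.24 ± 1.29 TPM, log2 1.61) were higher, and HOXA2 (log2 -1.15, adjusted p = 0.175) and GBX2 (log2 -0.61, adjusted p = 0.359) were not called. The lines differed again, with OTX2 at 82.6 TPM in line 26 and 50.7 TPM in line 48 and HOXA2 at 7.6 and 17 TPM. All 10 dorsal genes, 11 of 16 midbrain genes and 7 of 11 isthmus genes (8 over the list alone) were higher and none lower. These 3 lists stayed called with an estimated correlation (adjusted p = 0.00545, 0.00545 and 0.0274 with an estimated correlation). WNT feedback (7 higher of 13) and surface ectoderm (4 of 10) were called upward, and ventral (4 lower of 7), SOX B (3 of 4, SOX1 among them), cell cycle (6 of 14) and pan-neural (2 higher and 9 lower of 16) downward. None of these 6 kept the call (adjusted p = 0.0643, 0.0931, 0.0643, 0.0824, 0.264 and 0.0931 with an estimated correlation). Without SOX1 the SOX B list had 2 lower of 3 (adjusted p = 0.208 with an estimated correlation). Neuronal genes (4 lower of 14, with DCX (-1.21) and STMN2 (-1.34)), neural crest (3 higher, 1 lower of 12), NOTCH (1 and 4 of 11) and forebrain (3 and 4 of 16) were not called as lists. In all, 1210 genes were higher and 2779 lower, and 1644 and 1890 after median-ratio scaling, when neuronal genes had 2 higher and 4 lower and pluripotency 1 and 0 in place of 0 and 1. Fitted with only the libraries compared, 0 genes were called, with 5469 at unadjusted p < 0.05. The count of 3989 became 371 (without WT line 1), 1078 (without WT line 2) and 919 (without KO line 26). Not called when a line was left out were STMN2 (0.267, WT line 1), PAX2 (0.237, WT line 2), DCX (0.166, WT line 1), SHH (0.136, KO line 26), NES (0.126, WT line 1), TUBB3 (0.117, WT line 1), EN1 (0.0607, WT line 1) and NTN1 (0.0563, WT line 1), with the highest adjusted p.

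**Figure D2:**
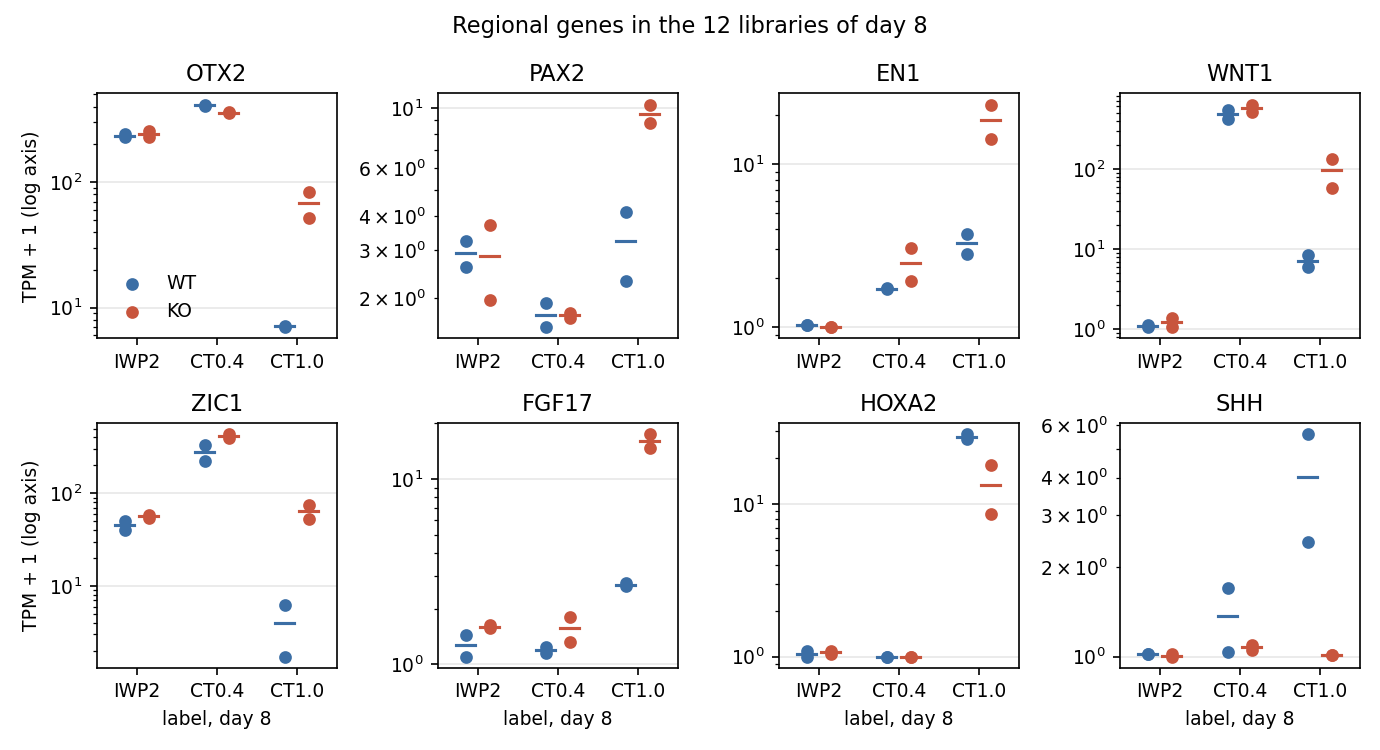
Regional genes in the 12 libraries of day 8, as TPM + 1 on log axes, with a short line at the mean of each group of 2. In CT1.0 the KO mean of OTX2 was 66.7 TPM and the WT mean 6.09 TPM; in IWP2 they were 243 and 234 TPM.

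Whether the KO effect itself depends on the label was tested as a difference of effects on day 8. From CT0.4 to CT1.0 the KO effect rose for OTX2 (log2 difference 3.41, adjusted p = 0.00257), WNT1 (log2 3.39, adjusted p = 0.00283), ZIC1 (log2 3.65, adjusted p = 0.00422), EN1 (log2 2.01, adjusted p = 0.0424) and FGF8 (log2 2.51, adjusted p = 0.009), and fell for TUBB3 (log2 -1.97, adjusted p = 0.0224) and SOX1 (log2 -2.16, adjusted p = 0.0276). HOXA2 (log2 -1.15, adjusted p = 0.436) was not called. Midbrain had 11 of 16 genes with a higher effect and none lower, dorsal 8 of 10 and isthmus 5 of 11 (adjusted p = 0.00512, 0.0134 and 0.0268 with an estimated correlation). The ventral list (0 higher, 1 lower of 7), neuronal (0 and 4 of 14), WNT feedback (1 and 0 of 13), NOTCH (0 called of 11) and surface ectoderm (0 called of 10) lost the call then (adjusted p = 0.191, 0.373, 0.181, 0.373 and 0.191 with an estimated correlation). In all, 433 genes had a higher effect and 852 a lower one, and 579 and 418 after median-ratio scaling. Leaving out 1 line changed the 1285 calls to 158 (without WT line 1), 129 (without WT line 2) and 367 (without KO line 26). Named genes whose call ended, with the highest adjusted p and the line left out, were EN1 (0.346, WT line 2), SOX1 (0.335, WT line 1), TUBB3 (0.268, WT line 1), FGF8 (0.224, WT line 2), WNT1 (0.138, WT line 2), ZIC1 (0.128, KO line 26) and OTX2 (0.102, WT line 2).

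Against IWP2 the effect in CT1.0 was higher for GDF7 (log2 difference 3.92, adjusted p = 0.000298), a roof plate signal, MSX2 (log2 3.93, adjusted p = 0.000732), OTX2 (log2 3.16, adjusted p = 0.00459) and EN1 (log2 2.54, adjusted p = 0.0187), and lower for NES (log2 -1.66, adjusted p = 0.0385) and SOX1 (log2 -3.00, adjusted p = 0.00634). Midbrain had 10 of 16 higher, dorsal 10 of 10 and isthmus 2 of 11 (7 over the list alone), all 3 kept with an estimated correlation (adjusted p = 0.00644, 0.00644 and 0.0471 with an estimated correlation). WNT feedback (1 higher of 13), surface ectoderm (3 of 10), ventral (1 lower of 7), SOX B (1 of 4, SOX1), pan-neural (2 higher, 3 lower of 16) and cell cycle (1 lower of 14) lost the call (adjusted p = 0.0899, 0.0899, 0.0805, 0.116, 0.116 and 0.458 with an estimated correlation). Without SOX1 the SOX B list had 0 called of 3 (adjusted p = 0.25 with an estimated correlation). In all, 254 genes had a higher and 646 a lower effect, and 343 and 363 after median-ratio scaling. With 1 line left out, the 900 calls became 124 (without WT line 1), 133 (without WT line 2), 340 (without KO line 26) and 1356 (without KO line 48). A left-out line ended the call of NES (0.396, WT line 1), EN1 (0.271, WT line 2), SOX1 (0.219, WT line 1), OTX2 (0.164, WT line 1) and MSX2 (0.0552, KO line 26), with the highest adjusted p given.

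Between CT0.4 and IWP2 the effect fell for EMX2 (log2 difference -2.71, adjusted p = 0.0346) and BARHL1 (log2 -2.24, adjusted p = 0.0377), and OTX2 (log2 -0.25, adjusted p = 0.996), SOX1 (log2 -0.84, adjusted p = 0.865) and EN1 (log2 0.53, adjusted p = 0.932) were not called. With the line as a block BARHL1 was not called (adjusted p = 0.06). The forebrain list fell with 2 of 16 lower (1 higher and 6 lower over the list alone; adjusted p = 0.000763 with an estimated correlation). SOX B (0 called of 4), pan-neural (0 of 16), NOTCH (0 of 11; 5 lower over the list alone), cell cycle (0 of 14) and, upward, dorsal (0 of 10) lost the call (adjusted p = 0.184, 0.187, 0.187, 0.202 and 0.44 with an estimated correlation). In all, 13 genes had a higher and 28 a lower effect. Dropping 1 line turned 41 calls into 106 (without WT line 1), 69 (without WT line 2), 162 (without KO line 26) and 157 (without KO line 48). The call ended for EMX2 (0.689, WT line 2) and BARHL1 (0.33, KO line 48) (highest adjusted p and the line left out).

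Averaged over the 3 labels within each line, the line means give the average effect of KO on a day, which the labels need not share. Values here are means ± SD of n = 2 lines, each averaged over labels on the log scale and turned back to TPM. On day 4 DDIT4 (289.6 ± 84.7 against 65.3 ± 3.74 TPM, log2 fold change 2.10, adjusted p = 0.0463), BHLHE40 (5.05 ± 0.22 against 0.471 ± 0.493 TPM, log2 2.08) and PFKFB4 (50.1 ± 9.17 against 13.4 ± 0.199 TPM, log2 1.81) were higher in KO. So were OTX2 (179 ± 12.3 against 82.9 ± 18 TPM, log2 1.11), WNT1 (9.79 ± 2.21 against 2.99 ± 0.0427 TPM, log2 1.42) and DMBX1 (12.5 ± 1.39 against 4.25 ± 0.0861 TPM, log2 1.36). For OTX2 this average mixes 3.5 in CT1.0, 0.06 in CT0.4 and -0.21 in IWP2. SOX1 (1.22 ± 0.807 against 9.74 ± 1.27 TPM, log2 -2.32) was lower, and EN1 (log2 1.27, adjusted p = 0.0604) and PAX2 (log2 1.12, adjusted p = 0.0828) were not called. Midbrain had 7 of 16 higher and cell stress 3 of 12, isthmus 0 of 11 and SOX B 1 lower of 4, which is SOX1, and these 4 called lists lost the call with another correlation (adjusted p = 0.196, 0.492, 0.641 and 0.479 with an estimated correlation). Without SOX1 the SOX B list had 0 called of 3 (adjusted p = 0.641 with an estimated correlation). The all-genes median was 0.12, with 229 genes higher and 10 lower, and 0.016 after median-ratio scaling, with 22 and 16, midbrain at 1 and 0 and cell stress at 0 and 0. With only the line means of day 4 fitted, 0 genes were called, with 5717 at unadjusted p < 0.05. Fits with 3 lines gave 0 (without WT line 1), 0 (without WT line 2), 2 (without KO line 26) and 22 (without KO line 48), against 239 with all 4. Calls lost on leaving out a line, with the highest adjusted p, were those of WNT1 (0.341, WT line 1), DDIT4 (0.321, WT line 1), SOX1 (0.309, WT line 1), PFKFB4 (0.278, WT line 1), BHLHE40 (0.269, WT line 1), DMBX1 (0.269, WT line 1) and OTX2 (0.268, WT line 1). Without the 4 WT day 4 CT libraries, which leaves IWP2 alone, 14 genes were called and OTX2 stood at -0.21.

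On day 8 no gene was called by line means, among them OTX2 (log2 1.02, adjusted p = 0.129), ZIC1 (log2 1.73, adjusted p = 0.161), WNT1 (log2 1.34, adjusted p = 0.137) and SOX1 (log2 -3.04, adjusted p = 0.0877). Limma called 0 genes, with 2572 at unadjusted p < 0.05. The count was 68 with no filter on low values, 16 with no intensity trend, 46 with library quality weights and 47 with protein-coding genes only. Adjusted over the list alone, 9 of 10 dorsal and 10 of 16 midbrain genes were higher, the latter with 2 lower. Both lists, with 10 others, were called by camera and lost the call (dorsal and midbrain adjusted p = 0.0752 and 0.0752 with an estimated correlation).

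Time in WT was read as the mean of the 3 labels. Values are means ± SD of n = 2 lines, each averaged over labels on the log scale on days 4 and 8 and turned back to TPM. This SD is between lines, and no single label need hold such a level. In the tests between days each library, not each line, was the replicate. If libraries of 1 line and day vary together, their p-values are too small. From ES to day 4 the pluripotency factor POU5F1 (42.9 ± 1.48 against 2457 ± 81.1 TPM, log2 fold change -5.81, adjusted p = 3.63e-12), with TDGF1 (0.158 ± 0.0336 against 262 ± 17.9 TPM, log2 -7.83) and the cadherin gene CDH1 (0.551 ± 0.258 against 96 ± 2.77 TPM, log2 -5.98), fell. PAX6 (35.5 ± 2.73 against 1.36 ± 0.18 TPM, log2 3.95), LRP2 (67.2 ± 2.24 against 1.61 ± 1.19 TPM, log2 4.79) and SOX1 (9.74 ± 1.27 against 0.221 ± 0.0619 TPM, log2 3.13) rose. OTX2 (log2 0.43, adjusted p = 0.304) was not called. Its average mixes unlike labels: against 60.8 ± 7.14 TPM in ES, day 4 held 159 ± 5.72 TPM in IWP2 and 8.19 ± 5.15 TPM in CT1.0. The day 4 average of SOX1 likewise mixes 0.949 TPM in IWP2 and 91 TPM in CT1.0. Pluripotency fell in 12 of 14 and pan-neural genes rose in 14 of 16, and forebrain had 8 higher and 1 lower of 16, all kept with an estimated correlation (adjusted p = 0.00186, 0.00177 and 0.00769 with an estimated correlation). Midbrain (10 higher of 16), rostral hindbrain (5 and 1 of 7), SOX B (3 of 4), neuronal (4 of 14), dorsal (5 of 10) and WNT feedback (7 and 1 of 13) were called upward, and surface ectoderm (1 and 5 of 10) and cell stress (0 and 7 of 12) downward, until the correlation was estimated (adjusted p = 0.174, 0.174, 0.174, 0.48, 0.48, 0.321, 0.174 and 0.174 with an estimated correlation). In all, 4523 genes were higher and 5564 lower. The count of 10087 became 6228 (without WT line 1) and 6420 (without WT line 2). Without the 4 WT day 4 CT libraries, which leaves IWP2 alone, the WNT feedback median turned from 0.86 to -0.30.

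From day 4 to day 8 ANXA1 (47 ± 5.32 against 0.289 ± 0.00452 TPM, log2 fold change 5.22, adjusted p = 7.86e-13), a phospholipid-binding protein gene, HES5 (42.6 ± 10 against 1.59 ± 0.53 TPM, log2 4.07), WNT3A (5.03 ± 0.943 against 0.0984 ± 0.0475 TPM, log2 2.45) and TUBB3 (309.7 ± 33.6 against 110.2 ± 10.4 TPM, log2 1.48) rose in WT. POU5F1 (1.41 ± 0.471 against 42.9 ± 1.48 TPM, log2 -4.20), PAX2 (1.52 ± 0.331 against 20.7 ± 1.21 TPM, log2 -3.12) and HES3 (9.94 ± 4.33 against 127 ± 6.67 TPM, log2 -3.60) fell. Pluripotency fell further in 8 of 14, and cell stress genes rose in 10 of 12 (adjusted p = 0.0174 and 0.0492 with an estimated correlation). Neuronal (10 higher of 14), dorsal (8 of 10), midbrain (10 and 1 of 16), pan-neural (10 and 4 of 16) and NOTCH (9 and 1 of 11) were called upward and isthmus (0 and 5 of 11) downward, until the correlation was estimated (adjusted p = 0.219, 0.219, 0.24, 0.219, 0.328 and 0.219 with an estimated correlation). The all-genes median was 0.16, with 6947 genes higher and 1637 lower, and 0.008 after median-ratio scaling, with 3761 and 3815. Cell cycle then turned from 8 higher and 2 lower of 14 to 2 and 6, and NOTCH went to 5 and 1. Leaving out 1 line changed the 8584 calls to 3989 (without WT line 1) and 4708 (without WT line 2). Without the 4 WT day 4 CT libraries, which leaves IWP2 alone, there were 3599 calls, the isthmus median turned to 0.84, the dorsal median to -0.05 and WNT3A to -0.02.

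The KO effect was higher on day 8 than on day 4 for ZIC1 (log2 difference 1.68, adjusted p = 0.0195), GDF7 (log2 1.53, adjusted p = 0.00412) and MSX2 (log2 1.31, adjusted p = 0.0193) and lower for DDIT4 (log2 -1.71, adjusted p = 0.0195) and PTCH1 (log2 -1.28, adjusted p = 0.0115). OTX2 (log2 -0.09, adjusted p = 0.919) and EN1 (log2 -0.29, adjusted p = 0.678) were not called. Each library was again a replicate, so p-values are too small if libraries of 1 line and day vary together. Dorsal genes had 4 of 10 higher (6 over the list alone), and cell stress 4 of 12, NOTCH 2 of 11, pan-neural 3 of 16 with 1 higher, ventral 1 of 7 and cell cycle 2 of 14 lower. All 6 lists were called and lost the call (adjusted p = 0.105, 0.399, 0.399, 0.399, 0.399 and 0.399 with an estimated correlation). The all-genes median was -0.13, with 87 genes higher and 721 lower, and -0.007 after median-ratio scaling, with 384 and 169. With 1 line left out, the 808 calls became 81 (without WT line 1) and 163 (without WT line 2). A left-out line ended the call of ZIC1 (0.236, KO line 26), DDIT4 (0.22, WT line 1), PTCH1 (0.162, WT line 1), MSX2 (0.144, KO line 48) and GDF7 (0.118, WT line 2), with the highest adjusted p given. There were 11 calls without the 4 WT day 4 CT libraries, when IWP2 alone remains, with PTCH1 at 0.02 and the ventral median at 0.03.

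Calls were also compared between pairs of comparisons that share no libraries. The pairs do share the 4 lines and 1 fit, with 1 variance per gene. A gene of low variance is called more readily in both. The counts for independent calls are therefore a reference and not a test. For KO against WT in CT1.0, 528 genes were higher on both days, where 150 would be shared by independent calls, and 351 were lower on both, where 69.1 would be. Of the day 4 higher genes 116 were lower on day 8 (344 if independent), and of the day 4 lower genes 11 were higher (30.1). On day 4, CT0.4 and CT1.0 shared 656 higher genes (127 if independent) and 70 lower genes (3.93). Both use the WT day 4 CT libraries, which stood apart, and had all-genes medians of 0.13 and 0.2. The shared higher calls may in part carry that common shift, and shared calls after median-ratio scaling were not counted. In CT0.4, days 4 and 8 shared 1 higher gene (1.62) and 1 lower gene (0.408). On day 8, CT0.4 and CT1.0 shared 6 higher genes (1.91) and 15 lower genes (7.17), and 14 genes lower in CT0.4 were higher in CT1.0 (3.12). Across genes, which are not independent replicates, fold changes of days 4 and 8 correlated at 0.267 in CT1.0 and 0.0223 in CT0.4, and those of CT0.4 and CT1.0 at 0.282 on day 4 and 0.0363 on day 8.

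**Figure D3:**
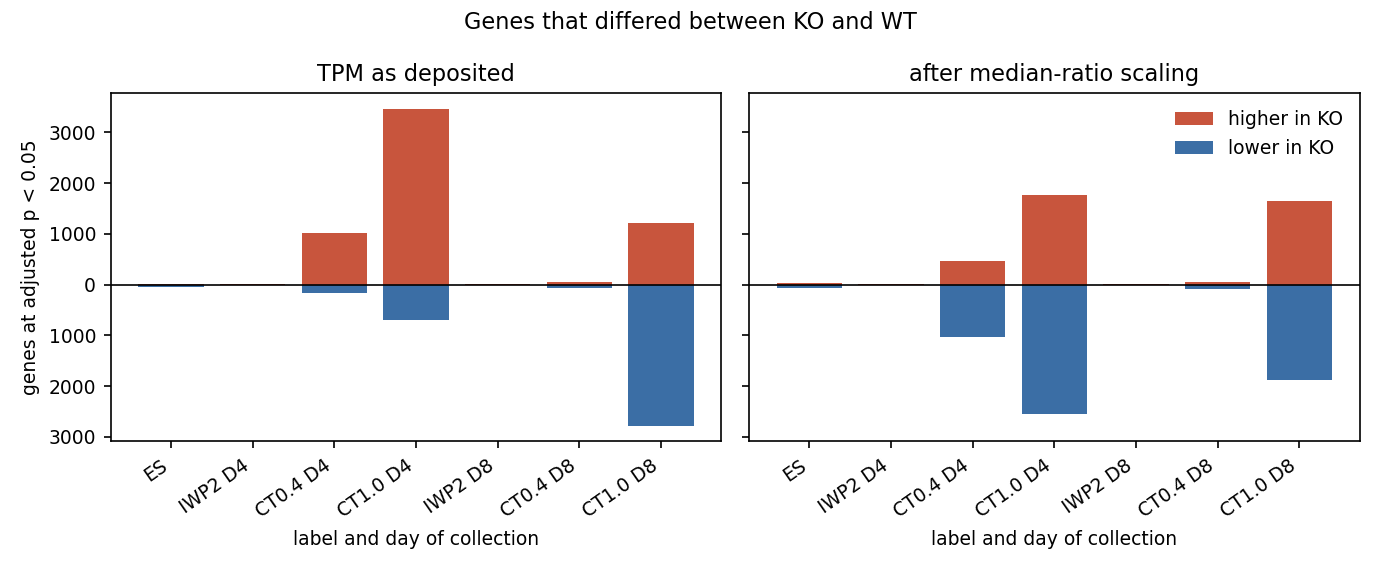
Genes called higher or lower in KO than in WT at adjusted p < 0.05 in the 7 comparisons of 2 libraries with 2, as deposited and after median-ratio scaling. In CT1.0 on day 4 the calls were 3453 higher and 694 lower as deposited and 1765 and 2547 after scaling.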

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

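The tests of culture conditions, of hypoxia genes in CT0.4 on day 8, of TPM scaling behind the upward skew, and of mixed cells were chosen only after the result was seen. What called for a closer look was that the KO effect itself differed between groups. Tested as a difference, with limma, it did so for 41 genes between CT0.4 and IWP2 on day 8, 900 between CT1.0 and IWP2, 1285 between CT1.0 and CT0.4, and 808 between day 8 and day 4.

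Genes that respond to low oxygen were higher in KO than in WT in both CT cultures of day 4. TPM scaling of the WT day 4 CT libraries is argued against: over the 20 members not looked at before, the median after median-ratio scaling lay above that of all genes by 0.702 in CT0.4 and 0.648 in CT1.0, where an upper percentile of 10000 random lists reached 0.091 and 0.114. For an effect in proportion to the SOX1 lost, the day 4 median was 0.025 higher in CT1.0 than in CT0.4, and the CT1.0 median of day 8 was 0.23. By the limits set before this test these left it undecided. The near-equal day 4 medians, 0.924 and 0.899, stood beside unlike losses of SOX1 (log2 -5.12 in CT1.0 and -1.67 in CT0.4). That argues against proportion for these 20 genes. CT0.4 also argues against it, where KO lacked more SOX1 on day 8 while the median changed by -0.75 from day 4, beyond the median SE of 0.235. Culture conditions that differed between the KO and WT CT cultures of day 4 cannot be told apart from the genotype, since how the cultures were grown side by side is not given in the sources used here. In IWP2 of that day the median was 0.01, and an effect of SOX1 loss specific to day 4 stays open too.

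Calls on day 4 in CT0.4 and CT1.0 were mostly higher in KO. With a trend on GC content or transcript length removed per library, the lower of both shares of higher calls was 84.5%. The removed trend was centred in each library, so the all-genes medians stayed at 0.13 in CT0.4 and 0.19 in CT1.0. A shift common to all genes was thus kept by construction, and the test cannot decide on this bias. After median-ratio scaling the higher of these shares was 40.9%, so lower calls then outnumbered higher ones in both labels. But that scaling sets the median of all genes near 0 and so moves the split whatever its source. TPM scaling of the WT day 4 CT libraries therefore cannot be told apart from a genotype effect on many genes, and no biological explanation of the skew was tested.

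The KO CT1.0 libraries of day 8 lay part of the way from WT CT1.0 to WT CT0.4. Swapped CT0.4 and CT1.0 labels are argued against, since the lowest position of a KO CT0.4 library was 0.996, where 1 is WT CT0.4. WT CT0.4 cells or RNA mixed in cannot raise a gene above both WT labels. Of 11 isthmus genes, 5 were higher by at least 1 (log2) in both KO libraries than in all 4 WT libraries of these labels. These genes argue against mixing as the only change, though they may be a second one. For the shift towards WT CT0.4 itself, mixing cannot be told apart from a change in the KO cells. A mixture with 1 common share was set against 83 genes abundant in WT CT0.4 and scarce in WT CT1.0. Its share, the median over these genes in TPM, ran from 0.0521 to 0.101 between pairs of KO and WT lines. Of the 83 genes, 11 lay 2-fold or more above the mixture, SP5 among them, and 6 below, PAX6 among them, 20.5% in all. This is under a limit of 25% that was set after the result was seen. A partial change of regional identity in both KO lines may account for it. On the log2(TPM + 1) scale, with genes chosen on WT line 1 and measured against WT line 2, lines 26 and 48 stood at 0.454 and 0.328 of the way. With the WT lines exchanged they stood at 0.377 and 0.222. Median shifts of genes higher and lower in CT0.4 were first 0.416 and -0.196 in line 26 and 0.237 and -0.064 in line 48. With the WT lines exchanged they were 0.116 and -0.399 in line 26 and 0 and -0.094 in line 48. The positions thus rest on part of the genes. The partial change is a hypothesis, found and tested on the same data, and a batch, which the labels do not give per library, stays open.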

How the results depend on the processing

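Protein-coding genes only, library quality weights, the correction for GC content and length, leaving out the 4 WT day 4 CT libraries, the SOX B list without SOX1, and line means fitted for 1 day alone or with a block were chosen only after the results were seen. Of the named genes' values under the alternatives, 2176 stayed on their side of the threshold, 387 lost the call, 20 gained one, 4 moved and 3 turned. The 2176 include values, uncalled in both fits, that changed sign by no more than 1 SE. The 4 were also uncalled in both and changed sign by more, and the 3 were called in at least 1 fit. List medians moved by less than their spread in 3914 cases, by more in 227, and turned in 7 for lists that were called. A change of sign in a list not called is counted under the first 2 of these. Camera calls with an estimated correlation were lost in 91 cases and unaltered in 232, and by fry 26 were lost and 32 gained. The counts below differ by over 1.5 times from those reported, others by less. The cause was not tested, except that fewer libraries, fewer genes or a minimum fold change act by their construction. D stands for day, a group without a genotype for KO against WT, and effect for the KO effect.

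With an absolute log2 fold change of at least 1: CT0.4 D4 1183 to 286, CT1.0 D4 4147 to 1401, CT1.0 D8 3989 to 1041 and line means D4 239 to 61. WT CT0.4 against IWP2 D8 3400 to 1685, WT CT1.0 against IWP2 D8 3013 to 1252, WT CT1.0 against CT0.4 D8 3989 to 1704, WT CT1.0 against IWP2 D4 5596 to 1619, WT D4 against ES 10087 to 4166 and WT D8 against D4 8584 to 1336. Effect CT1.0 less IWP2 900 to 464, effect CT1.0 less CT0.4 1285 to 651 and effect D8 less D4 808 to 126. With only the libraries of the groups compared: ES 61 to 146, IWP2 D4 12 to 0 (2188 at unadjusted p < 0.05), CT0.4 D4 1183 to 0 (4257 at unadjusted p < 0.05), CT1.0 D4 4147 to 334, IWP2 D8 17 to 120 and CT1.0 D8 3989 to 0 (5469 at unadjusted p < 0.05). WT CT0.4 against IWP2 D8 3400 to 814, WT CT1.0 against IWP2 D8 3013 to 785, WT CT1.0 against CT0.4 D8 3989 to 762 and WT CT1.0 against IWP2 D4 5596 to 1748. Effect CT0.4 less IWP2 41 to 79, effect CT1.0 less IWP2 900 to 95 and effect CT1.0 less CT0.4 1285 to 95. SOX1 was then not called in CT0.4 D4 (-1.67, adjusted p = 0.251), CT1.0 D4 (-5.12, adjusted p = 0.0879), CT0.4 D8 (-2.60, adjusted p = 0.455) and CT1.0 D8 (-4.76, adjusted p = 0.132). With no filter on low values: ES 61 to 239, IWP2 D4 12 to 43, IWP2 D8 17 to 53, CT0.4 D8 116 to 207 and line means D8 0 to 68. Effect CT0.4 less IWP2 41 to 91. The rostral hindbrain median in ES went from -0.53 to 0. With median-ratio scaling: ES 61 to 99, IWP2 D8 17 to 11 and line means D4 239 to 38. WT CT1.0 against IWP2 D4 5596 to 3337. With no intensity trend and robust variances: CT0.4 D4 1183 to 768, line means D4 239 to 46 and line means D8 0 to 16. Effect CT1.0 less IWP2 900 to 531 and effect CT1.0 less CT0.4 1285 to 849. With a pseudocount of 0.1: effect CT0.4 less IWP2 41 to 27. The midbrain median in WT CT1.0 against IWP2 D4 crossed 0, at 0 to 2 decimals in both. With protein-coding genes only: IWP2 D4 12 to 0 (1445 at unadjusted p < 0.05), IWP2 D8 17 to 2, line means D4 239 to 589 and line means D8 0 to 47. Effect CT0.4 less IWP2 41 to 13 and effect CT1.0 less IWP2 900 to 1432. With library quality weights: line means D4 239 to 1731 and line means D8 0 to 46.

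Without the 4 WT day 4 CT libraries, when averages use IWP2 alone: IWP2 D8 17 to 11, line means D4 239 to 14 and line means D8 0 to 1. WT D8 against D4 8584 to 3599. Effect CT0.4 less IWP2 41 to 22 and effect D8 less D4 808 to 11. Turned were OTX2 in line means D4 (1.11 to -0.21), WNT3A in WT D8 against D4 (2.45 to -0.019), PTCH1 in the effect D8 less D4 (-1.28 to 0.02), and the medians of WNT feedback in WT D4 against ES (0.86 to -0.30), isthmus and dorsal in WT D8 against D4 (-0.33 to 0.84 and 1.88 to -0.046) and ventral in the effect D8 less D4 (-0.55 to 0.026). Corrected for GC content and length, CT0.4 D4 had 1265 calls and CT1.0 D4 4453. Without SOX1 the SOX B list kept its preset-correlation result, called or not, in 13 of 13 comparisons of KO.

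Leaving out each line in turn gave: ES 63 to 149, IWP2 D4 47 to 143, CT0.4 D4 109 to 755, CT1.0 D4 1023 to 3330, IWP2 D8 47 to 118, CT0.4 D8 71 to 215, CT1.0 D8 371 to 4318, line means D4 0 to 22 and line means D8 0 to 0. WT CT0.4 against IWP2 D8 983 to 3522, WT CT1.0 against IWP2 D8 731 to 3115, WT CT1.0 against CT0.4 D8 1255 to 4040, WT CT1.0 against IWP2 D4 1194 to 5503, WT D4 against ES 6228 to 10116 and WT D8 against D4 3989 to 8718. Effect CT0.4 less IWP2 69 to 162, effect CT1.0 less IWP2 124 to 1356, effect CT1.0 less CT0.4 129 to 1534 and effect D8 less D4 81 to 794. SOX1 ran over ES -0.28 to -0.18, IWP2 D4 -0.47 to 0.14, CT0.4 D4 -1.89 to -1.45, CT1.0 D4 -5.75 to -4.49, IWP2 D8 -1.93 to -1.58, CT0.4 D8 -2.98 to -2.21 and CT1.0 D8 -5.16 to -4.35. The NOTCH median in the effect CT1.0 less CT0.4 ran over -0.025 to 0.567, from 0.29 to -0.025 without KO line 48. A group left with 1 library is assumed to vary like the other groups.

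At adjusted p < 0.01 shared calls went from 528 to 178 higher and 351 to 97 lower for CT1.0 D4 and D8, 1 to 0 and 1 to 0 for CT0.4 D4 and D8, 656 to 199 and 70 to 9 for CT0.4 and CT1.0 D4, and 6 to 0 and 15 to 5 for CT0.4 and CT1.0 D8. With the line as a block, no count moved by over 1.5 times. In the 7 comparisons of KO and WT by group the block was random, and its consensus correlation of 0.00112 left that fit almost unaltered, so it tests little there. Elsewhere the block was fixed: BARHL1 in the effect CT0.4 less IWP2 lost its call (adjusted p = 0.06), and no other call of a named gene changed. Fitted for 1 day alone, line means D4 went from 239 to 0 (5717 at unadjusted p < 0.05), and with a random block (consensus correlation -0.0159) 236 on day 4 and 0 on day 8. No value can be given for the 3 comparisons that need the 4 WT day 4 CT libraries when these are left out. TPM keeps no depth, so how far depth limits the low genes is unknown.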

Other observations

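Genes that respond to low oxygen, 34 of them listed after the first results were seen, were counted as a list. The values of 14 had been seen when the list was made, so those of the other 20 are given beside the whole. In KO against WT on day 4, limma called 26 higher in CT0.4 and 29 in CT1.0, with 0 lower and medians of 1.32 and 1.45 (26 and 25 higher after median-ratio scaling). Of the 20, 12 and 15 were higher, with medians of 0.90 and 0.92. VEGFA, an angiogenic signal, had 71 ± 9.41 against 15.7 ± 2.42 TPM in CT0.4 and 131 ± 25.1 against 23.1 ± 4.27 TPM in CT1.0 (n = 2). HK2, a glycolytic enzyme, had 73 ± 15.8 against 25.7 ± 2.35 TPM and 66.3 ± 4.28 against 17.7 ± 0.572 TPM. These genes were chosen after their values were seen. In CT1.0 on day 8, 16 of the 34 were higher and 3 lower, with a median of 0.60, and 7 and 2 of the 20, with a median of 0.23 and a median SE of 0.235. None was called in IWP2 on day 4 (median 0.13) or day 8 (median -0.05) or in CT0.4 on day 8 (median 0.10), and in ES cells 0 were higher and 3 lower (median -0.45), and 0 of the 20 called (median -0.29). In WT 2 rose and 21 fell from ES to day 4 (2 and 12 of the 20). In WT on day 4, 16 were higher and 3 lower in CT1.0 than in IWP2 (median 0.46, and 0.75 after median-ratio scaling), and 7 and 2 of the 20 (median -0.02, and 0.26 after it).

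The KO lines stood apart in CT1.0. On day 4 EN1 stood at 39.9 TPM in line 26 and 17.9 TPM in line 48, and at 3.09 and 1.76 TPM in WT lines 1 and 2. WNT1 stood at 50.5 and 25.6 TPM in the KO lines on day 4 and at 132 and 57.6 TPM on day 8, where the WT lines held 7.48 and 4.98 TPM. GBX2, a gene of the anterior hindbrain, stood at 1.79 and 5.76 TPM in the KO lines on day 4 and at 11.9 and 9.37 TPM in the WT lines. The difference between the KO lines was not tested.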
